A study of Rattus norvegicus with 8 samples.

How the data were processed

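MicroRNA levels in rat kidney were measured on 8 one-colour (Cy3) Agilent rat miRNA arrays, 4 from sham-operated and 4 from nephrectomized rats. Per the labels' protocols, RNA was purified with the miRNeasy Mini Kit and labelled with Agilent's miRNA Complete Labeling Reagent and Hyb Kit. Groups and replicate numbers were taken from the sample titles. The study's design text speaks of 4 rats, so each array was taken as 1 rat. The sample labels give day 1 for the sham kidneys and day 2 for the nephrectomized kidneys, whereas the design text names 2 days, so the time after surgery may differ between the groups.

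The deposited scanner tables hold intensity values on a linear scale, written by Agilent Feature Extraction 12.0.3.1 per the file headers. The processed intensity of a spot is background-subtracted and spatially detrended per the file headers, and can be below 0. The deposited tables also hold other columns of 0 or 1, which mark detected miRNAs, spots well above background, saturated spots and outlier spots. The deposited value table of the series holds log2 values. Its scale, centring and direction are not given in the sources used here, and were found from the values: each value is the log2 total signal of a miRNA, with an undetected miRNA set to 0.1, shifted by a constant per array and centred on the median of the miRNA. Values rebuilt in this way differed from the deposited log2 values by at most 1.3e-05, and only the rule behind the shift per array stays unknown. The column medians of that table ran from -0.25 to -0.052 in the sham arrays and from 0.052 to 0.17 in the nephrectomized arrays. It has 637 entries, of which 623 are miRNAs and 14 are controls, and it was used as an alternative.

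Each array held 12128 spots for 1806 probes of 758 miRNAs and 715 control spots. Control spots and outlier spots were left out, the latter 8.10% to 9.01% of the spots per array, and no spot was saturated. Spots of a probe were averaged, then the 1 to 4 probes of a miRNA. Each array was divided by its 75th percentile over the 214 miRNAs detected on all 8 arrays and multiplied by the mean of the 8 percentiles. Values under a floor of 0.925 were set to the floor (5 values in 4 tested miRNAs), and log2 was taken. Detection was Feature Extraction's call per miRNA. The 238 miRNAs detected on at least 4 of the 8 arrays were tested; 26 detected on 1 to 3 arrays and 494 detected on none were not. Among 196 tested miRNAs with at least 2 probes above 4 times the floor, the probes of 32 disagreed in the sign of the difference.

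Differences were tested with limma 3.58.1 (lmFit and eBayes, group as the only term) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A difference is given as nephrectomized minus sham on the log2 scale of the floored signal. The floor can understate the change only of the 4 tested miRNAs with a value at the floor. A miRNA detected on no array of a group has only a bound there: the mean of the other group was set against the mean over arrays of the higher of the lowest signal of a detected miRNA and the miRNA's own signal. For the miRNAs named here that were lost on every nephrectomized array, their own signal was the higher, so the fold given is the measured difference and bounds nothing. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.067. Measures of whole arrays were compared with exact two-sided permutation tests, whose smallest p with 4 against 4 arrays is 0.0286. Their p-values were adjusted over the 4 measures by Benjamini-Hochberg.

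Lists of miRNAs were fixed before the data were examined: kidney-enriched miRNAs, the miR-30, let-7, miR-29, miR-200, miR-34 and miR-181 families, the family of miR-15, miR-16 and miR-195, the miR-99/100 and miR-125 families, the miR-17-92 and paralogous clusters, kidney injury and inflammation, hypoxia, the Dlk1-Dio3 imprinted cluster, and markers of red blood cells, leukocytes, endothelium, smooth muscle and fibroblasts, striated muscle, liver and neurons. Lists with at least 3 tested members were tested with limma's camera at its preset correlation, Benjamini-Hochberg adjusted over the lists, and also with an estimated correlation and with fry, in 1 direction and mixed. Unlike camera, fry tests the members of a list without setting them against the other miRNAs. The rule for the miRNAs named here was fixed at the same time: those past the threshold, filled up to 20 by the lowest p, then the 3 members of each list with the lowest p, and 12 kidney or cell type miRNAs. A miRNA named outside this rule is said to be so. Positions are those of the longest probe of a miRNA in the rat genome build rn4, as the deposited files give them, counted from 1; some miRNAs have none there. Annotation of the same build was not used here.

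The fit was tested on simulated data for the 238 miRNAs, with noise drawn independently for each miRNA and no error in the scaling. Over 50 runs with 60 miRNAs changed, it recovered 66.3% of changes of 0.25, 89.8% of changes of 0.5 and 96.8% of changes of 1 on the log2 scale, with 3.89% false calls. These rates hold for that setting. Fewer changed miRNAs, correlated noise or an error in the scaling were not simulated and could give other rates. In a separate simulation of 100 runs, also with independent noise, camera called 5.25% of unshifted lists at an unadjusted p under 0.05. Members of a list can be correlated on real arrays, so this rate does not show how often camera errs here. Alternatives covered the scaling, background correction, summary of spots and probes, floor, filter on dim miRNAs, replicate number as a block, variance model, array weights, the deposited value table and leaving out each array. Scaling by the labelling spike-ins, leaving out miRNAs with GC-rich probes, and the alternatives for the array-wide signal were added after the data were seen. All 8 arrays lie on 1 slide and share 1 scan, so no slide effect could be fitted. The sham arrays fill row 1 of the slide and the nephrectomized arrays row 2, so row and group cannot be told apart. Summaries and tests of single values were computed in Python 3.11.15 with SciPy 1.17.1 and pandas 2.3.3.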

Results

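MicroRNA levels were measured in the right kidneys of 8 male F344/NSlc rats, an inbred Fischer strain, at an age of 10 weeks. Of these, 4 rats had a sham operation and 4 had lost the other kidney. The kidney left after such an operation takes over the work of the missing one and enlarges, which is called compensatory growth, and the comparison asks which miRNAs differ in it. The labels place the sham kidneys at day 1 and the nephrectomized kidneys at day 2 after surgery, so time and surgery cannot be told apart if these labels are right. Each array measured 758 miRNAs, of which 242 to 253 were detected on a sham array and 224 to 230 on a nephrectomized array. The 10 brightest miRNAs, led by let-7a-5p, let-7f-5p, let-7c-5p, let-7b-5p and miR-26a-5p, chosen here by their signal, held 45.0% ± 0.690 (SD, n = 4) of the summed signal in sham kidneys and 45.0% ± 0.416 (SD, n = 4) in nephrectomized kidneys.

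miR-21-5p, a miRNA known for its induction in injured and fibrotic kidney, was among the brightest miRNAs and stood at a log2 level of 11.07 ± 0.042 (SD, n = 4) in nephrectomized kidneys and 10.85 ± 0.058 (SD, n = 4) in sham kidneys. That difference is 1.16-fold, and every nephrectomized array lay above every sham array. miR-130b-3p had the lowest p, with log2 levels of 3.13 ± 0.25 and 2.30 ± 0.19 (SD, n = 4), a 1.78-fold difference at a level close to the limit of detection. miR-93-5p, a member of the growth-linked miR-106b-25 cluster, stood at 6.46 ± 0.028 and 6.31 ± 0.025 (SD, n = 4), 1.11-fold. miR-26a-5p, an abundant miRNA known to restrain proliferation, was lower, at 11.51 ± 0.033 in nephrectomized and 11.63 ± 0.034 (SD, n = 4) in sham kidneys. None of these differences passed the test after adjustment.

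The log2 differences were +0.22 ± 0.042 (SE) for miR-21-5p and +0.83 ± 0.14 for miR-130b-3p, each with a limma Benjamini-Hochberg adjusted p of 0.0667. For miR-667-3p, of the imprinted Dlk1-Dio3 cluster, the difference was +0.34 ± 0.063, with the same adjusted p. miR-93-5p differed by +0.15 ± 0.032 (limma adjusted p = 0.0763) and miR-26a-5p by -0.12 ± 0.035 (limma adjusted p = 0.130). miR-340-5p was detected on 4 of 4 sham arrays and 0 of 4 nephrectomized arrays, with a measured signal 1.29-fold higher in sham kidneys (limma adjusted p = 0.0672). The longest probes of these miRNAs lie, in build rn4, on chromosome 10 from 74864520 to 74864538 (miR-21-5p), chromosome 11 from 85885650 to 85885666 (miR-130b-3p), chromosome 6 from 134400564 to 134400576 (miR-667-3p), chromosome 12 from 17608195 to 17608209 (miR-93-5p) and chromosome 8 from 123981642 to 123981656 (miR-26a-5p).

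**Figure D1:**
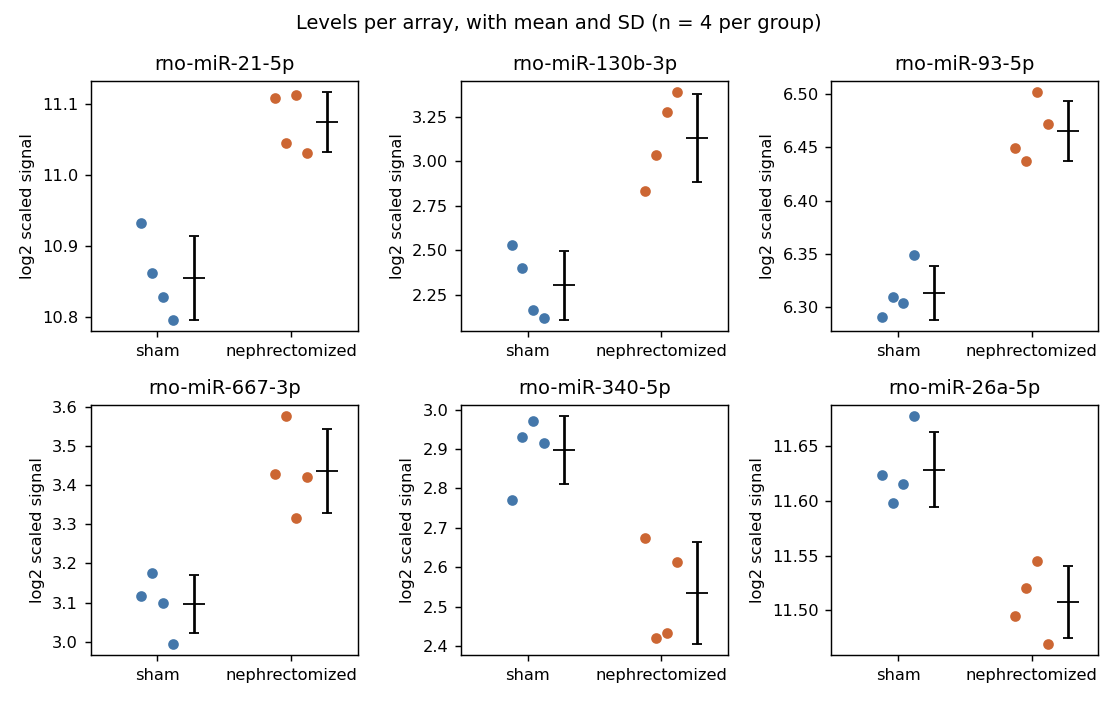
Log2 scaled signal of 6 miRNAs on each sham array and each nephrectomized array, with the mean and SD of 4 arrays per group. The groups do not overlap in any panel, and miR-21-5p differs by 0.22 on the log2 scale.

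Of the other miRNAs with the lowest p, 12 were higher in nephrectomized kidneys and 2 were lower. The higher ones were miR-1896, at +0.53 ± 0.12 (SE), miR-6216 at +0.38 ± 0.091, miR-2985, miR-3085, miR-1188-3p, miR-425-3p, miR-3544, miR-3549, miR-6333, miR-298-5p, miR-3573-3p and let-7b-3p, and their log2 differences ran from +0.21 to +0.53. The lower ones were miR-503-5p, at -0.36 ± 0.099, and miR-195-5p, at -0.11 ± 0.032, both relatives of miR-15 and miR-16, which repress cell cycle genes. In limma with Benjamini-Hochberg adjustment, 0 of 238 tested miRNAs passed the threshold of 0.05 and 11 lay under 0.10. At an unadjusted p under 0.05 there were 48, of which 37 were higher and 11 lower. limma's variance model with a trend and robust fitting called 7: miR-21-5p, miR-130b-3p, miR-1896, miR-6216, miR-2985 and miR-667-3p as higher and miR-26a-5p as lower. The groups did not overlap for 35 miRNAs (14.7%, where chance gives 2.86%), 25 of them higher and 10 lower. The 95% interval excluded a 2-fold change for 230 miRNAs (96.6%). Each interval covers a single miRNA and takes the scaling as exact. For 2 tested miRNAs the log2 difference exceeded 1 in size, without passing the threshold.

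**Figure D2:**
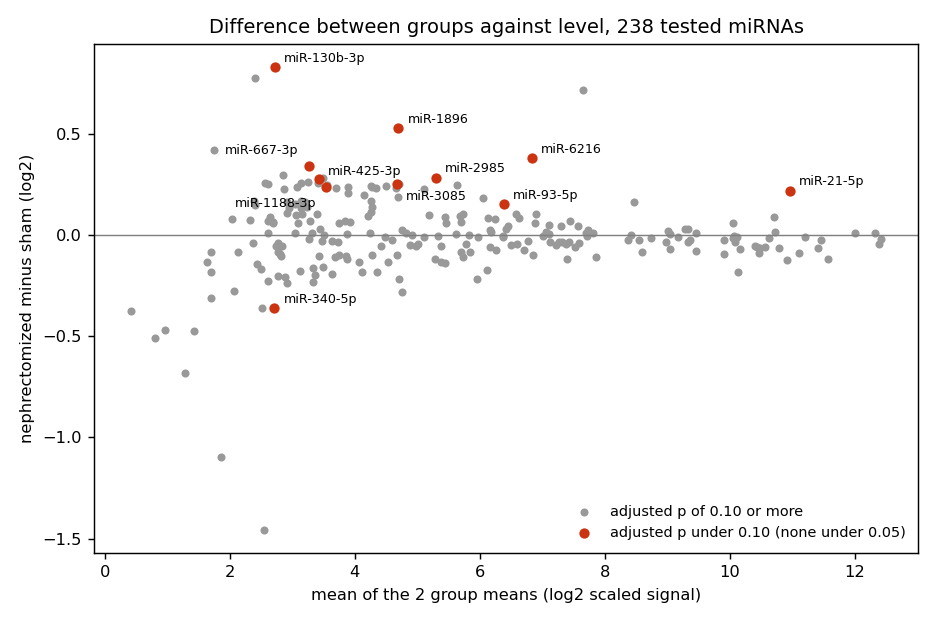
Difference between nephrectomized and sham kidneys (log2) against the mean of the 2 group means (log2 scaled signal) for the 238 tested miRNAs, with the 11 at an adjusted p under 0.10 in red. Most differences are small, with a median size of 0.084, and 8 of them exceed 0.5 in size.

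The number and direction of differences depended on the scaling. The counts of higher and lower miRNAs at an unadjusted p under 0.05 were 31 and 23 with scaling to the median, 20 and 89 with the percentile taken over all miRNAs, 1 and 172 without scaling, 37 and 21 with quantile normalization, 140 and 21 with normexp background correction, and 33 and 1 with scaling to the labelling spike-ins. The median difference over all tested miRNAs was -0.0077 and moved to -0.11 with the percentile over all miRNAs, to -0.29 without scaling and to +0.13 with normexp. Without scaling, miR-21-5p stood at -0.063 and miR-93-5p at -0.13, both above that median, and with normexp miR-340-5p stood at +0.17.

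Among miRNAs linked to growth, miR-93-5p was the single one of 10 tested members of the miR-17-92 and paralogous clusters to pass when adjusted over the list alone (limma adjusted p = 0.0165), and 0 passed over all miRNAs. Its cluster partners miR-106b-5p and miR-25-3p, the latter named after its value was seen, differed by +0.057 ± 0.042 and +0.051 ± 0.045 (SE). In the family of miR-15, miR-16 and miR-195, whose members hold back the cell cycle, 2 of 7 passed when adjusted over the list alone, in opposite directions, and 0 over all miRNAs. These were miR-15b-5p at +0.16 ± 0.051 and miR-195-5p at -0.11 ± 0.032, each with a limma adjusted p of 0.0416 over the list. In the let-7 family, 0 of 12 members passed either way, and let-7a-5p, let-7b-5p and let-7c-5p, named for their signal, stood at -0.023, +0.0077 and +0.0070. The star arms let-7b-3p and let-7d-3p differed by +0.24 ± 0.074 and +0.26 ± 0.092. The 3 tested members of the p53-regulated miR-34 family had differences below 0 (a median of -0.096, and of +0.19 with normexp), with miR-34a-5p at -0.083 ± 0.079 (-0.13 to -0.0083 when 1 array was left out), and 0 passed either way.

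miR-29, a family known to repress collagens and other matrix genes, was lower as a group: all 5 tested members had differences below 0, with a median of -0.13, or -0.15 to -0.10 when 1 array was left out (limma camera, adjusted p = 0.0375). The call was lost with a data-based correlation, where the list had an adjusted p = 0.601 with an estimated correlation. The members miR-29a-3p, at -0.13 ± 0.044 (SE), and miR-29c-3p, at -0.095 ± 0.043, are near-identical in sequence, and 0 members passed over all miRNAs or adjusted over the list alone. The group lay below the other miRNAs under all 26 alternatives, while its member miR-29a-5p stood at +0.20 with normexp. The epithelial miR-200 family and the kidney-abundant miR-30 family had 6 of 6 and 9 of 10 members below 0 and did not pass (limma camera, adjusted p = 0.113 for each). Their medians were -0.12 and -0.050, and turned to +0.00042 for miR-200 with normexp and to +0.037 for miR-30 with scaling to the labelling spike-ins, where the median of all tested miRNAs was +0.080. Examples are miR-200c-3p at -0.23 ± 0.093, miR-141-3p at -0.22 ± 0.093, miR-200b-3p at -0.034 ± 0.045 and miR-30a-5p at -0.067 ± 0.034, and 0 members of either family passed over all miRNAs or adjusted over the list alone.

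The Dlk1-Dio3 cluster, an imprinted domain with a large group of miRNA genes, was higher as a group, with 8 of 9 tested members above 0 and a median of +0.16, or +0.064 to +0.24 when 1 array was left out (limma camera, adjusted p = 0.0375). That call was also lost, with an adjusted p = 0.669 with an estimated correlation. When adjusted over the list alone, 4 members passed (miR-667-3p, miR-299a-5p, miR-668 and miR-409a-3p, the last named after its value was seen, from +0.23 to +0.34), and 0 over all miRNAs. Here 86 miRNAs of the cluster are on the array, so 9 tested members are a small part of it. The group lay above the other miRNAs under all 25 alternatives that could test it, although its median was -0.12 without scaling, where the median of all miRNAs was -0.29. The probes of miR-667-3p, miR-668 and miR-409a-3p are GC-rich, at 71.4%, 69.2% and 71.4%. Over all tested miRNAs, those with a probe GC content of at least 60% had a median difference of +0.10 and those below 40% of -0.058.

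**Figure D3:**
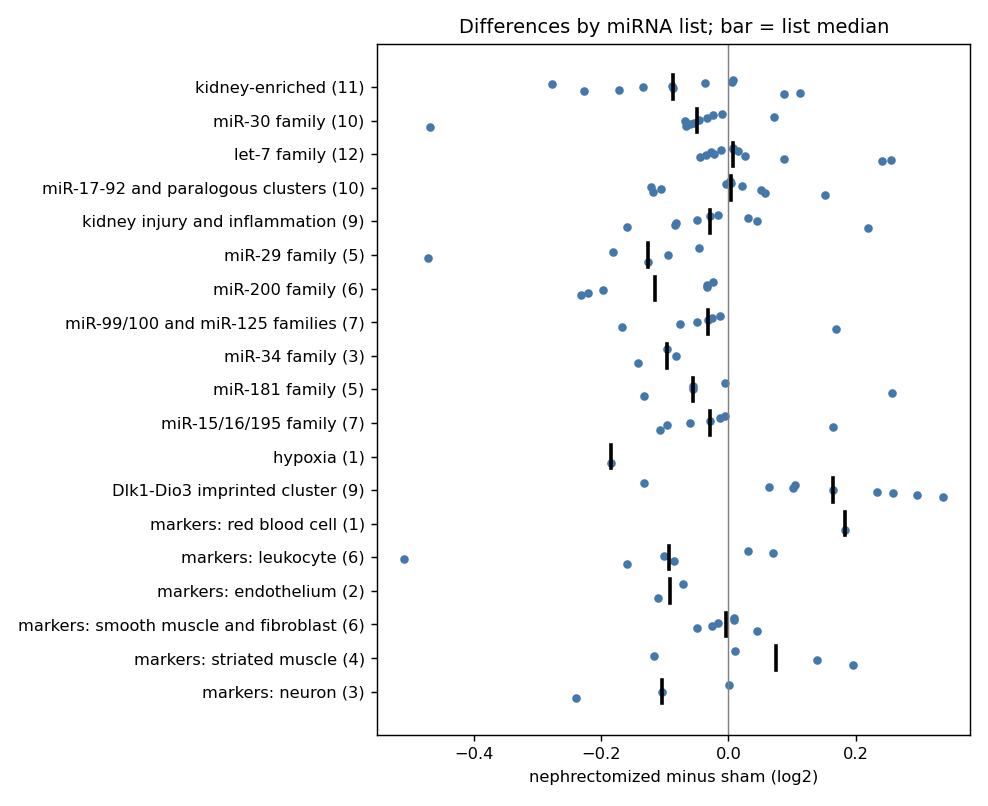
Difference between nephrectomized and sham kidneys (log2) for each tested miRNA of each list, with the number of tested members in brackets and the list median as a bar. The miR-29 family has a median of -0.13 and the Dlk1-Dio3 cluster one of +0.16.

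Kidney-enriched miRNAs gave no call as a group in a common direction. miR-192-5p, a tubular miRNA, differed by +0.088 ± 0.030 (SE) and miR-194-5p, its cluster partner, by +0.0057 ± 0.032, while miR-204-5p stood at -0.13 ± 0.083 (-0.18 to -0.058 when 1 array was left out) and miR-10a-3p at -0.23 ± 0.10. miR-192-5p turned to -0.017 with the percentile taken over all miRNAs and to -0.19 without scaling. Of 11 tested members, 0 passed over all miRNAs or adjusted over the list alone, and the list did not pass for a shift in 1 direction (limma camera, adjusted p = 0.499). fry's mixed test, which takes changes in both directions together, passed this list with an adjusted p of 0.0241. It does not set the list against other miRNAs. At an unadjusted limma p under 0.05 there were 2 of the 11 members, against 48 of all 238 tested miRNAs, a similar share. In the list of kidney injury and inflammation, miR-21-5p alone of 9 tested members passed when adjusted over the list alone (limma adjusted p = 0.00757), and 0 over all miRNAs. miR-155-5p and miR-146a-5p, 2 inflammation miRNAs, differed by -0.16 ± 0.069 and -0.084 ± 0.042. miR-210-3p, the classic hypoxia miRNA, differed by -0.18 ± 0.090 (limma adjusted p = 0.288), or by -0.23 to -0.093 when 1 array was left out. In the miR-99/100 and miR-125 families (7 tested) and the miR-181 family (5 tested) 0 members passed either way, with medians of -0.033 and -0.055, and the miR-181 mean was +0.0018.

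Of the marker lists, 4 had enough tested members for a list test and 0 passed; those of endothelium (2 tested), red blood cells (1) and liver (0) could not be tested as lists. With no filter, endothelium could be tested and was called lower, and red blood cells could be tested and were not called (limma camera, adjusted p = 0.0419 and 0.827). With an estimated correlation the endothelium call was lost (adjusted p = 0.175). The erythrocyte miRNA miR-451-5p varied widely between rats, at 6.15 ± 0.53 in nephrectomized and 5.97 ± 0.59 (SD, n = 4) in sham kidneys, a difference of +0.18 ± 0.35 (SE). Leukocyte markers had a median of -0.093 over 6 tested members, with miR-223-3p at +0.031 ± 0.042 and miR-150-5p at -0.085 ± 0.053 (limma camera, adjusted p = 0.477). The endothelial miR-126a-3p and miR-126a-5p differed by -0.072 ± 0.037 and -0.11 ± 0.051. Smooth muscle and fibroblast markers had a median of -0.0039 over 6 members, with miR-145-5p at -0.025 ± 0.062 and miR-214-3p at +0.046 ± 0.048. Striated muscle markers (4 tested, miR-1-5p at +0.20 ± 0.090) and neuron markers (3 tested, miR-9a-5p at -0.24 ± 0.17, or -0.36 to -0.090 when 1 array was left out) had camera adjusted p of 0.649 and 0.591 in limma. The liver miRNA miR-122-5p was detected on 0 of 8 arrays. Over these marker lists 0 miRNAs passed over all miRNAs, and 0 adjusted over the list alone.

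The nephrectomized arrays were dimmer and detected fewer miRNAs. The mean number of detected miRNAs was 226.5 ± 2.65 (SD, n = 4) on nephrectomized arrays and 246.8 ± 4.65 on sham arrays. The log2 of the 75th percentile used for scaling was 7.40 ± 0.095 and 7.68 ± 0.11 (SD, n = 4). The labelling spike-ins, synthetic RNAs added before the labelling reaction, averaged 10.19 ± 0.18 and 10.56 ± 0.036 on the log2 scale, a difference of -0.37 ± 0.091 (SE). Hybridisation spike-ins, added labelled before hybridisation, averaged 13.33 ± 0.023 and 13.37 ± 0.0083, a difference of -0.038 ± 0.012 (SE). For each of these 4 measures the groups did not overlap, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays can give, and the same value after Benjamini-Hochberg adjustment. Detection was lost on all 4 nephrectomized arrays for 4 miRNAs detected on all 4 sham arrays: miR-340-5p, miR-653-5p, miR-450b-5p and miR-1843a-5p, the last 3 named after their values were seen. For these 3, the measured sham levels were 1.24-fold (miR-1843a-5p), 1.14-fold (miR-653-5p) and 1.06-fold (miR-450b-5p) higher, with limma adjusted p of 0.462, 0.584 and 0.805. The reverse held for 0 miRNAs.

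**Figure D4:**
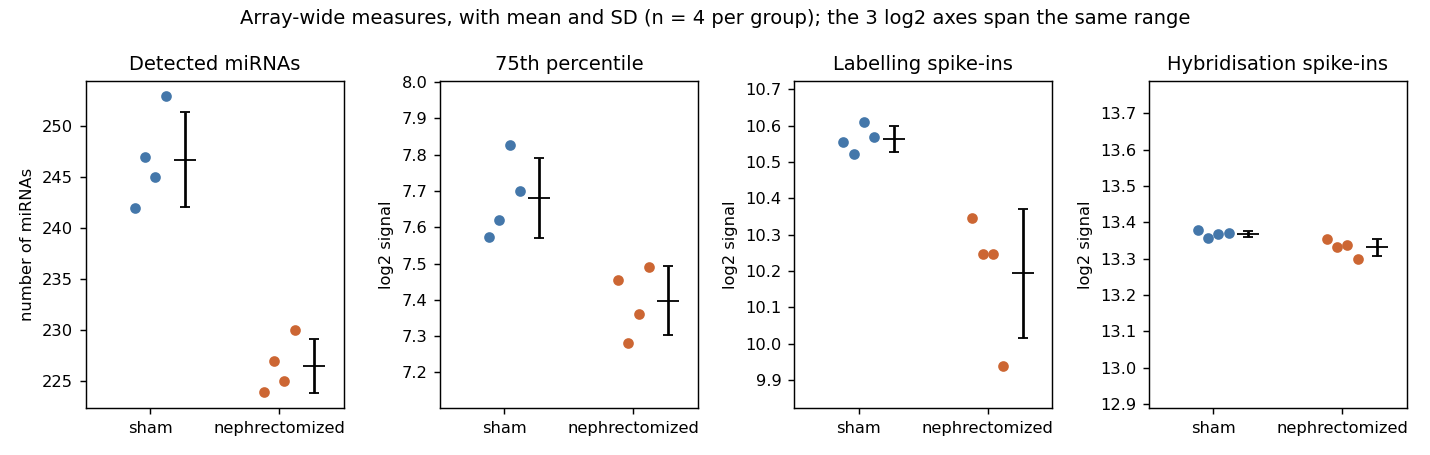
Number of detected miRNAs, log2 of the 75th percentile, and log2 signal of the labelling and hybridisation spike-ins on each array, with the mean and SD of 4 arrays per group. The groups do not overlap in any panel, and the labelling spike-ins differ by -0.37 and the hybridisation spike-ins by -0.038.

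The named miRNAs miR-30a-5p, miR-29a-3p, miR-29c-3p, miR-19b-3p, miR-100-5p, miR-133b-3p, miR-200b-3p, miR-200c-3p, miR-204-5p, miR-181c-5p, miR-181d-5p, miR-299a-5p, miR-7a-5p, let-7a-1-3p, let-7a-5p, let-7b-5p, let-7c-5p and let-7f-5p each share a probe sequence, up to 1 mismatch or a shift of 1 base, with another miRNA on the array, so their values can hold signal of that relative. The shortest probes were not compared in this way, so the list can be incomplete.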

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

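All tests here followed rules fixed before the data were examined. The levels of the 70 named miRNAs and the 4 measures of whole arrays were searched, group by group, for an array that stood far from the other 3. Of 148 groups of 4 arrays, 4 had such an array, where chance gives 1 in 20 (7.4), so the number is no more than chance gives. miR-100-5p had a log2 level of 6.10 on the array of nephrectomized replicate 1, and 6.26 to 6.29 on the other 3. miR-150-5p, a lymphocyte miRNA, stood at 5.66 on that same array, and at 5.85 to 5.87 on the others of its group. miR-299a-5p had a level of 2.76 in nephrectomized replicate 4, against 3.07 to 3.09. miR-9a-5p, known from neurons, had 3.28 in sham replicate 4, against 2.94 to 2.96. Outside the tested miRNAs, miR-339-5p was detected on 1 nephrectomized array and 0 sham arrays, and was not tested.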

How the results depend on the processing

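Scaling to the labelling spike-ins, leaving out miRNAs whose longest probe has a GC content of 50% or more, and all alternatives for the array-wide signal were chosen after the data were seen. miR-130b-3p was higher under all 26 alternatives (+0.27 to +0.93) and past the threshold in 11, with limma adjusted p from 0.00304 to 0.223. miR-21-5p was higher under 25 of 26, without scaling being the exception, and past the threshold in 7, with limma adjusted p from 0.00356 to 0.438. miR-195-5p was lower under all 26 (-0.39 to -0.021) and past the threshold in 4, with limma adjusted p from 0.00102 to 0.975. The miR-29 family was called lower in 10 of 26 alternatives (camera adjusted p from 0.000614 to 0.402) and the Dlk1-Dio3 cluster higher in 13 of 25 (0.00446 to 0.486). Over all named miRNAs, 1550 of 1775 values kept their sign and side of the threshold, 128 kept their sign and passed it, and 97 turned sign, 26 of them past it. Signal over background limits the dim miRNAs: the median residual SD was 0.156 in the dimmest 25% and 0.051 in the brightest 25%. The slide could not be fitted as a block, since there was 1 slide.

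With the replicate number as a block, 0 miRNAs passed (47 at an unadjusted p under 0.05) and 1 list did, the Dlk1-Dio3 cluster; it changed no other call than that of the miR-29 family (camera adjusted p = 0.101). Arrays of the same number correlated at 0.053, -0.077, 0.28 and -0.23 in their deviations from the group means. These values show no sign of pairing by number, though so few cannot exclude it. Of all 8 arrays, only sham replicate 3 correlated best with its own number.

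The limma count of 0 miRNAs past the threshold (48 at an unadjusted p under 0.05) became 19 (1 higher, 18 lower) with the percentile over all miRNAs, 161 (1 higher, 160 lower) without scaling, 156 (136 higher, 20 lower) with normexp, 1 with quantile normalization (miR-195-5p), 7 with total gene signal (3 higher, 4 lower), 5 with the deposited value table (1 higher, 4 lower), 15 with the brightest probe (all higher), 4 with a floor 4 times higher (all higher), 1 with miRNAs detected on all 8 arrays (miR-130b-3p), 7 with a trended and robust variance model (6 higher, 1 lower), 3 with array weights (2 higher, 1 lower), 1 with scaling to the labelling spike-ins (miR-130b-3p) and 3 without GC-rich probes (miR-130b-3p and miR-21-5p higher, miR-340-5p lower). It stayed at 0 with scaling to the median, a floor 4 times lower, and filters at 1 array or none. Without scaling, with the percentile over all miRNAs, and with scaling to the median or to the labelling spike-ins, all differences move together by construction, apart from values at the floor. normexp added an offset of 50 to each signal before the scaling, which weighs most on dim miRNAs. The offset was the same on every array, while the array-wide signal was lower on the nephrectomized arrays (7.40 against 7.68, log2). Dividing by the percentile therefore moves dim miRNAs upwards there by construction, whatever their own difference. Signs that turned above 0 with normexp are thus weak evidence against a fall. How much of each normexp value this explains was not tested, nor was the cause for the other settings. Leaving out 1 array gave 0 to 5 miRNAs: 5 without nephrectomized replicate 3 and 1 without nephrectomized replicate 1. The count of 2 lists became 1 with the percentile over all miRNAs, without scaling, with the brightest probe and with miRNAs detected on all 8 arrays, 0 with quantile normalization, total gene signal, the deposited table, the higher floor, the filter at 1 array, scaling to the labelling spike-ins or without GC-rich probes, 0 with an estimated correlation and with fry in 1 direction, 3 with normexp (the miR-29, miR-30 and let-7 families, all lower, and not the Dlk1-Dio3 cluster) and 4 with no filter (the miR-29, miR-30 and miR-200 families and endothelium, all lower); with an estimated correlation 0 lists passed in any setting, and fry's mixed test passed 4 lists (the family of miR-15, miR-16 and miR-195, kidney injury, kidney-enriched and the Dlk1-Dio3 cluster, adjusted p from 0.00198 to 0.0299); leaving out 1 array gave 0 to 2, with 0 without sham replicate 4, nephrectomized replicate 2 or nephrectomized replicate 3. The difference in detected miRNAs ran from -21.8 to -18.2 and that in array-wide signal from -0.32 to -0.23 when 1 array was left out, where the exact permutation p cannot go below 0.0571. The array-wide difference was -0.18 with the percentile over all miRNAs, at an exact permutation p of 0.0571.

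Single miRNAs that turned sign are listed here and below only where the fixed rule named them. Values that turned below 0 without scaling were miR-21-5p (-0.063), miR-93-5p (-0.13), miR-3085 (-0.029), miR-1188-3p (-0.045), miR-425-3p (-0.0041), miR-3544 (-0.039), miR-3549 (-0.050), miR-6333 (-0.026), miR-298-5p (-0.075), miR-3573-3p (-0.045), let-7b-3p (-0.041), miR-192-5p (-0.19), miR-192-3p (-0.17), let-7d-3p (-0.027), let-7a-1-3p (-0.19), miR-106b-5p (-0.22), miR-99a-3p (-0.11), miR-181a-1-3p (-0.025) and miR-15b-5p (-0.12). The same held for miR-668 (-0.023), miR-451-5p (-0.099), miR-214-3p (-0.24), miR-1-5p (-0.086), miR-133b-3p (-0.14), miR-128-3p (-0.28), miR-194-5p (-0.28), miR-223-3p (-0.25) and the let-7 family (median -0.27). Among miRNAs named outside the rule, miR-25-3p (-0.23), let-7b-5p (-0.27) and let-7c-5p (-0.27) are examples that also turned below 0 without scaling. With the percentile over all miRNAs, the miRNAs of the fixed rule that turned below 0 were miR-192-5p (-0.017), let-7a-1-3p (-0.017), miR-106b-5p (-0.048), miR-214-3p (-0.059), miR-128-3p (-0.10), miR-194-5p (-0.099) and miR-223-3p (-0.074). The let-7 family (-0.098) and the miR-17-92 clusters (-0.10) also turned below 0.

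With normexp, values turned above 0 for miR-340-5p (0.17), miR-503-5p (0.16), miR-10a-3p (0.18), miR-30c-1-3p (0.19), miR-155-5p (0.14), miR-29a-5p (0.20), miR-200c-3p (0.14), miR-141-3p (0.070), miR-200b-5p (0.15), miR-125a-3p (0.17), miR-100-5p (0.018), miR-34c-5p (0.19), miR-34a-5p (0.041), miR-34b-5p (0.19), miR-181d-5p (0.12), miR-181c-5p (0.13), miR-322-3p (0.13), miR-210-3p (0.11), miR-150-5p (0.036) and miR-342-5p (0.20). The same held for miR-126a-5p (0.026), miR-199a-5p (0.011), miR-145-5p (0.13), miR-499-5p (0.045), miR-9a-5p (0.16), miR-7a-5p (0.16) and miR-204-5p (0.039), and for the medians of the miR-34 family (0.19), the miR-181 family (0.12) and neuron markers (0.16), while miR-194-5p stood at -0.036. camera's direction turned for the let-7 family (-0.053) and the miR-17-92 clusters (0.066).

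Scaling to the labelling spike-ins turned miR-30a-5p (0.020), miR-30c-5p (0.028), miR-146a-5p (0.0031), miR-100-5p (0.011), miR-34a-5p (0.0044), miR-181c-5p (0.032), miR-150-5p (0.0026), miR-126a-3p (0.015), miR-199a-5p (0.039), miR-145-5p (0.062) and miR-200b-3p (0.053) above 0, and camera's direction for the miR-17-92 clusters (0.091). Quantile normalization turned miR-30c-5p (0.013), miR-128-3p (-0.015) and miR-223-3p (-0.038), scaling to the median miR-128-3p (-0.029) and miR-194-5p (-0.024), and the brightest probe miR-145-5p (0.049). Total gene signal turned miR-99a-3p (-0.12) and miR-181a-1-3p (-0.50), and camera's direction for the injury list (-0.029) and for smooth muscle and fibroblast markers (-0.0039). The deposited table turned miR-99a-3p (-0.16), miR-181a-1-3p (-2.45), miR-128-3p (-0.043), miR-194-5p (-0.038) and miR-223-3p (-0.012). Array weights turned the miR-17-92 clusters (-0.0050). Without GC-rich probes, camera's direction turned for the miR-17-92 clusters (-0.12), the injury list (-0.029), the family of miR-15, miR-16 and miR-195 (-0.014) and smooth muscle and fibroblast markers (-0.0039). Leaving out 1 array gave ranges across 0 for miR-451-5p (-0.030 to 0.41), miR-145-5p (-0.060 to 0.0064), miR-128-3p (-0.021 to 0.035), miR-194-5p (-0.0074 to 0.016), and the medians of the miR-17-92 clusters (-0.023 to 0.047), smooth muscle and fibroblast markers (-0.024 to 0.0097), the let-7 family (-0.0052 to 0.032), the injury list (-0.067 to 0.0048), the miR-99/100 and miR-125 families (-0.052 to 0.0064) and the miR-181 family (-0.066 to 0.014); the median of neuron markers came close to 0 (-0.19 to -0.0059).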

Other observations

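Of the tests reported here, those on the deposited value table and on the count past the adjusted threshold were chosen after the result was seen, as was the use of the whole gap as the bound in the test of less miRNA per unit of RNA. Single abundant miRNAs of the kidney, named for their signal, held these mean shares of the summed signal. let-7f-5p held 6.90% ± 0.274 (SD, n = 4) in sham and 6.78% ± 0.119 in nephrectomized kidneys, and let-7g-5p 3.00% ± 0.032 and 3.02% ± 0.12. miR-21-5p held 2.35% ± 0.086 and 2.77% ± 0.104, miR-192-5p 2.06% ± 0.0175 and 2.23% ± 0.041, and miR-26a-5p 4.01% ± 0.0814 and 3.74% ± 0.060. These shares were not tested.

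miR-3473, named after its values were seen, gave +0.71 ± 0.22 (SE) between the groups (limma adjusted p = 0.131). Its log2 level was 8.29, 8.33 and 8.12 in nephrectomized replicates 1, 2 and 4 but 7.29 in replicate 3, inside the sham range of 7.15 to 7.47. miR-1896 and miR-6216 were also lowest in that rat among the nephrectomized, at 4.60 and 6.75. Without nephrectomized replicate 3, miR-3473 stood at +0.95 and was 1 of 5 miRNAs past the threshold, with miR-1896, miR-6216, miR-328a-5p, also named after its values were seen, and miR-667-3p (limma adjusted p = 0.00149 for the lowest).

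The number of miRNAs at an unadjusted p under 0.05 was 48, and 1 of the 35 splits of the 8 arrays into 4 and 4 gave as many, the real one. The highest other count was 39. A share of 1 in 35 is the smallest these splits can give, so chance is unlikely for this count but not excluded. For the limma count past the adjusted threshold, 0 here, all 35 splits must give as many (highest other count 1), so this decides nothing. For the 2 called lists, 7 of 35 splits gave as many, with a highest other count of 5, and chance cannot be excluded.

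The nephrectomized arrays had a lower array-wide signal, by -0.28 on the log2 scale. The hybridisation spike-ins differed by -0.038 ± 0.012 (SE), which argues against hybridisation, washing or scanning as the cause of the whole gap. The labelling spike-ins differed by -0.37 ± 0.091 (SE), so weaker labelling of the nephrectomized samples is a candidate explanation. Within the nephrectomized group, however, replicate 4 had the lowest labelling spike-ins (9.94) but the highest array-wide signal (7.49) on the log2 scale. Relative to the labelling spike-ins, the array-wide signal differed by +0.087 ± 0.13 (SE), more than 2 standard errors above the -0.28 that less miRNA per unit of total RNA, or a smaller RNA input, would need as the whole cause, while a part stays open. The row of the slide coincides with the groups, and a biological difference by surgery or day stays open as untested.

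A set of 37 mostly dim miRNAs was higher in nephrectomized kidneys at an unadjusted p under 0.05 by nearly the same amount, with a median of +0.24 and quartiles of 0.23 and 0.26, and by -0.041 without scaling. Their median sham log2 level was 4.15 and their median probe GC content 62.5%. Low level was not particular to them: the 11 lower miRNAs had medians of 3.57 and 45%. The other 190 tested miRNAs had medians of 5.44 and 47.4%. Over all tested miRNAs the difference rose with the GC content of the probe (Spearman rho = 0.323 across miRNAs, which are not independent; permutation p = 1e-05, the smallest these permutations can give). Within groups, the unscaled signal of the 37 followed the array-wide level with a median slope of 0.219 (95% bootstrap interval 0.086 to 0.36), against 0.785 for the other tested miRNAs. The interval was drawn over miRNAs that share the same arrays, so it does not hold the uncertainty from the arrays. A part of the signal that does not scale with labelled RNA, lifted by the scaling, would give a low slope. If stronger on GC-rich probes, it would also give such a rho. The slope does not involve GC content, and 20 of the 37 had a probe GC content of at least 60%. That class was also the dimmest, with a median sham log2 level of 3.79, so GC content and level were not told apart. A true rise of these miRNAs stays open, and miR-21-5p and miR-130b-3p, with probe GC contents of 40% and 44.4%, lie outside the GC-rich class.

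In the deposited value table, 4 miRNAs stood at -6.25 (miR-340-5p), -5.09 (miR-653-5p), -5.23 (miR-450b-5p) and -5.22 (miR-1843a-5p) on the log2 scale, the lowest of all. From the probe signals their median difference was -0.25 (range -0.36 to -0.083), and none was detected on a nephrectomized array. The deposited values were rebuilt with 0.1 in place of the signal of an undetected miRNA. The nephrectomized values of these 4 miRNAs are thus that substitute, shifted and centred, and falls of this size come from it. In the same table, 368 miRNAs detected on no array each stood +0.23 higher in nephrectomized kidneys, the shift between arrays alone. A smaller true fall of these 4 miRNAs stays open.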
